A study of Mus musculus with 2 samples.

How the data were processed

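Total RNA depleted of ribosomal RNA was sequenced from the nuclear fraction of mouse bone-marrow-derived macrophages, primary cells of the C57BL/6J strain. The cells had been given Lipid A at 100 ng/ml for 12 h, washed and left without it for 12 h, and given Lipid A at 100 ng/ml again for 120 min. Lipid A is the part of bacterial lipopolysaccharide that the receptor TLR4 recognises. The labels give 2 biological replicates of this 1 condition and the same donor label for both, so whether they came from separate animals is not stated, and the spread between them may be partly technical. The labels name the fraction nucleus in one field and nucleoplasmic in another. The starting RNA was 1 µg for replicate 1 and 500 ng for replicate 2, so the input amount and the replicate cannot be told apart. Unstimulated cells, cells stimulated once and other fractions were not analysed here, and no comparison between conditions was made.

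Each sample had a gene table, a transcript table and a second transcript table. Per the file headers, the deposited gene and transcript tables held expected counts (estimated counts that need not be whole) and TPM (a length-corrected share of all transcripts), with column names as RSEM writes them. The authors' second transcript table held estimated counts and TPM with column names as kallisto writes them; it is called the second tool here. The tools, their versions, the aligner and the strand setting were not given in the sources used here. The deposited tables also gave posterior mean TPM and the bounds of a credibility interval for each TPM, which are other estimates from the same reads. Per the file headers the reference was mm10 with GENCODE release M21. All 55536 mouse gene identifiers of the gene tables were matched to that annotation, from which symbols, gene types and coordinates (mm10, counted from 1) were taken.

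The expected counts on genes summed to 28450309 in replicate 1 and 16940220 in replicate 2. Rows that name no mouse gene were left out of library sizes and tests. The phiX174 sequence had 518475 counts in replicate 1, 1.79% of all counts, and 54031 in replicate 2, 0.318%. The 96 ERCC spike-in rows had 0 counts in both, and the 26248 predicted tRNA rows had 18 and 28 counts. A gene with 0 counts may still have been present at up to 3 counts, which is a CPM of 0.105 in replicate 1 and 0.177 in replicate 2. Such floors, and the 95% Wilson intervals given for shares of counts, cover counting error only, because PCR copies were not marked. The difference between length and effective length in the gene tables put the mean fragment at 237 nt in replicate 1 and 218 nt in replicate 2.

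Levels are given as deposited TPM, as the mean of the 2 libraries ± SD (n = 2). Short structural RNAs took most of the TPM (values in the results), so a TPM of another gene depends on how much of them a library held. A small SD of 2 TPM values therefore does not by itself show that the replicates were close. A gene was called detected at TPM 1 or more in both libraries. The spread between replicates was estimated with edgeR 4.0.16 in R 4.3.3 as the common biological coefficient of variation of an intercept-only model, on expected counts rounded to whole numbers, with TMM scaling and genes with a mean count of 10 or more. Each such gene was also compared between the libraries with an exact two-sided binomial test on the rounded counts given the TMM-scaled library sizes, with Benjamini-Hochberg adjustment and a threshold of 0.05. That test covers counting error only and compares these libraries, not conditions. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

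Before the data were examined, 23 gene lists for macrophage programmes and RNA classes, 9 marker lists of other cell types and the replication-dependent histone genes were fixed, 33 in all. A list's level was its median TPM, set against 10000 random lists of the same size from protein-coding genes, or from non-coding genes for non-coding lists. Its shift between the libraries was the median log2 ratio of TPM + 1, replicate 2 over replicate 1, set against 10000 random lists matched on mean expression in 20 bins. The same was done with TMM-scaled counts and a prior count of 0.5. Between the libraries the median log2 ratio of all tested genes was 0.43 on the TPM scale and 0.00 (0.0046) on TMM-scaled counts, so every shift is given relative to that median. The retained-intron share was the share of a gene's TPM on transcripts that the annotation types as retained intron, for genes with a mean count of 10 or more and at least 1 such transcript. The symbols Mb21d1 and Snhg4 were not found in the annotation, and for Rmrp, Mirt2 and Aldoa, which have several identifiers, the one with the highest mean count was used. Nuclear copies of mitochondrial DNA were taken as pseudogenes with a mean count of 10 or more of which 80% or more of the 31-base words occur in mitochondrial transcripts. GC content was that of a gene's longest transcript.

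The genes named were set by a rule fixed before the data were examined. It took 20 index genes of the Lipid A response, the 3 members of each list with the highest mean TPM, the 10 genes with the highest mean TPM among those with an effective length of 200 or more, and the 3 with the highest expected count. It also took, among genes with a mean count of 100 or more past the binomial test, the 5 with the largest ratio in each direction, and the 5 detained-intron genes with the highest retained-intron share. Of the genes this rule took, 2 are not reported here. Other genes named beside them were chosen after their values were seen.

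The alternatives were DESeq2 1.42.0 size factors or library size in place of TMM, its fitted dispersion, other count and TPM minimums, other pseudocounts, the second tool, posterior mean TPM, TPM rescaled over genes with an effective length of 200 or more outside the mitochondrial genome, and each library alone. Matching random lists on GC content was added after the data were seen. On simulated data for the replicate dispersion, a coefficient of 0.3 put into 14768 genes was estimated as 0.302. For the binomial test, 200 of 14757 simulated genes were changed: it found 36% of those changed by 1.25-fold, 64% at 1.5-fold, 80% at 2-fold and 96% at 4-fold, and it called 5 unchanged genes. For the list shift, 4.75% of simulated lists of 20 genes without a shift fell outside the middle 95% of random lists. The simulated counts for the binomial test held counting error only. The simulated list values were independent between genes apart from a trend with expression. A trend with GC content and genes that vary together were not simulated, so these rates need not hold for the real libraries.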

Results

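Nuclear RNA was measured in bone-marrow-derived macrophages that met Lipid A a second time, 12 h after a first exposure of 12 h had been washed out, and were collected 120 min into the second exposure. There was 1 group with 2 biological replicates, at 28450309 and 16940220 expected counts on genes. The design has no control group, so the data show which RNAs the nuclear fraction held and how far the replicates differed, and not what the treatment changed. The purity of that fraction was not measured. Genes of the mitochondrial genome took 4.15% of its counts in replicate 1 and 10.3% in replicate 2.

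By counts, protein-coding genes made up most of these libraries, from which ribosomal RNA had been depleted. Those of the nuclear genome took 69.5% ± 4.47 (SD, n = 2) of the expected counts. The long non-coding RNA Malat1, which resides in nuclear speckles, took 9.16% ± 1.26 by itself and had the most counts of any gene, followed by Rn7sk, the RNA that holds the elongation factor P-TEFb inactive, and mt-Co1. Malat1's own share was 8.27% in replicate 1 (95% Wilson interval 8.26 to 8.28) and 10.06% in replicate 2 (10.04 to 10.07). Short structural RNAs took 7.99% ± 3.41 of the counts and genes of the mitochondrial genome 7.23% ± 4.35. The other long non-coding RNAs took 3.70% ± 0.881.

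TPM gave another picture, because it divides by effective length, which raises the values of short RNAs. Short structural RNAs held 64.8% ± 15.1 of the TPM and protein-coding genes of the nuclear genome 19.7% ± 2.90. Rn7sk alone had 300056 ± 64364 TPM, Rpph1, the RNA of ribonuclease P, 80329 ± 33788 TPM, and Rmrp, the RNA of ribonuclease MRP, 56861 ± 24186 TPM. Rmrp has a near-identical second annotated gene at the same place, so its reads are split between the 2 and its value is uncertain.

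**Figure D1:**
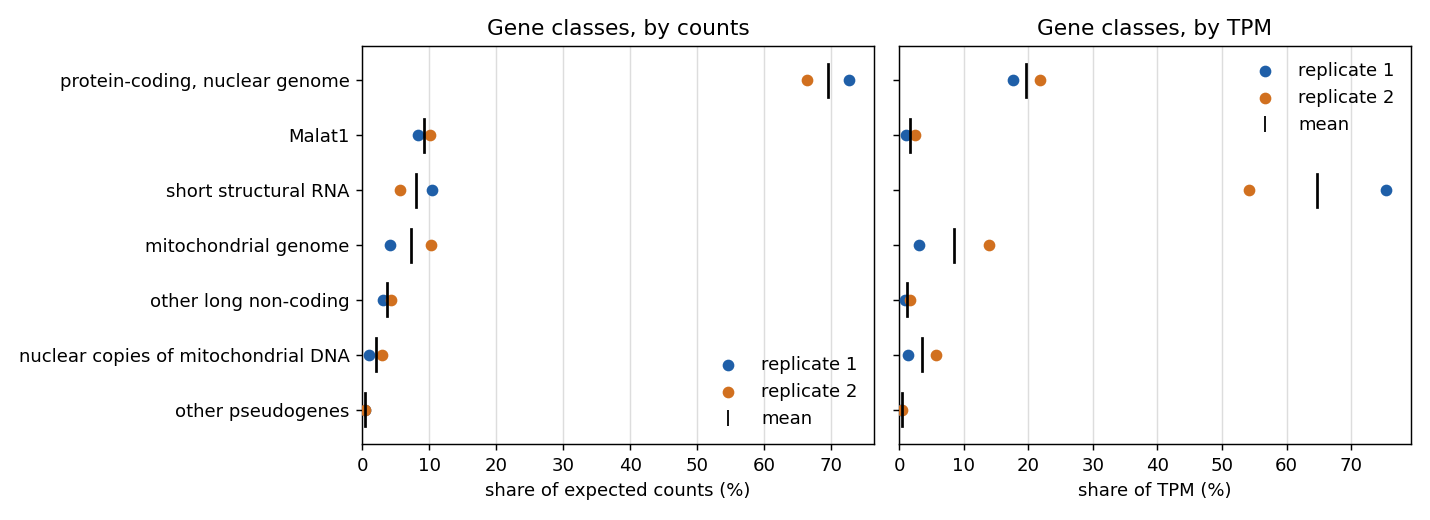
Share of each library taken by each gene class, by expected counts (left, %) and by TPM (right, %); points are the 2 replicates and black bars their mean. Protein-coding genes lead by counts (69.5% on average) and short structural RNAs by TPM (64.8%), and the mitochondrial genome's share of counts was 4.15% in replicate 1 and 10.3% in replicate 2.

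Among genes with an effective length of 200 or more, the 2 highest were Malat1 and mt-Co1. Malat1 (chromosome 19, 5795690 to 5802672, mm10) had 17255 ± 9680.0 TPM and the mitochondrial mt-Co1, a subunit of cytochrome c oxidase, 20374 ± 13873 TPM. The other 8 of the top 10 were 5 more mitochondrial mRNAs (mt-Nd6, mt-Nd1, mt-Cytb, mt-Nd5 and mt-Nd4, from 4425 to 5198 TPM) and the pseudogenes Gm28661, Gm10925 and Gm28437. These pseudogenes lie side by side on chromosome 1 from 24613189 to 24615565 and are copies of mitochondrial DNA, so their reads cannot be told from those of the mitochondrial genome. The gene tables gave Gm28661 11034 ± 7780.3 TPM, and they gave Gm10925 3391 TPM in replicate 1 and 14509.7 in replicate 2. The second tool gave Gm10925 94.8 and 24.0 TPM, so the tools differ on which library was higher.

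The nuclear fraction held transcripts of 10437 genes at TPM 1 or more in both libraries, of which 8726 were protein-coding and 1150 long non-coding, out of 55536 genes in the tables. Across all genes, unexpressed ones included, log2(TPM + 1) of the 2 libraries had a Pearson correlation of 0.972 and a Spearman correlation of 0.923. For genes with a mean count of 10 or more these were 0.957 and 0.951, and with the second tool 0.949 and 0.937 over all genes. Genes are not independent replicates. The replicates' common biological coefficient of variation was 0.335 over 14698 genes.

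Messenger RNAs of inflammatory cytokines and chemokines were present in the nuclear fraction 120 min into the second exposure. Of the 32 listed genes, 25 had TPM 1 or more in both libraries, 7 had 100 or more and 6 were below 1 in both. The list's median was 19.6 ± 2.496 TPM, at percentile 100 of random lists of protein-coding genes in both libraries. The chemokines Ccl5 (1415 ± 63.0 TPM), Cxcl10 (532 ± 74.5 TPM; chromosome 5, 92346638 to 92348889) and Ccl4 (501 ± 93.8 TPM) led the list. Tnf, the cytokine of early inflammation (chromosome 17, 35199381 to 35202007), had 422 ± 9.91 TPM, and Il1b (chromosome 2, 129364570 to 129371139) had 82.4 ± 20.3 TPM. Il12b, a subunit of interleukin-12, had 29.1 ± 8.98 TPM and Il6 13.5 ± 3.54 TPM. The anti-inflammatory Il10 had 5.39 ± 1.62 TPM. Interferon beta, Ifnb1 (chromosome 4, 88522025 to 88522774), had 15.8 TPM in replicate 1 and 4.38 in replicate 2.

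**Figure D2:**
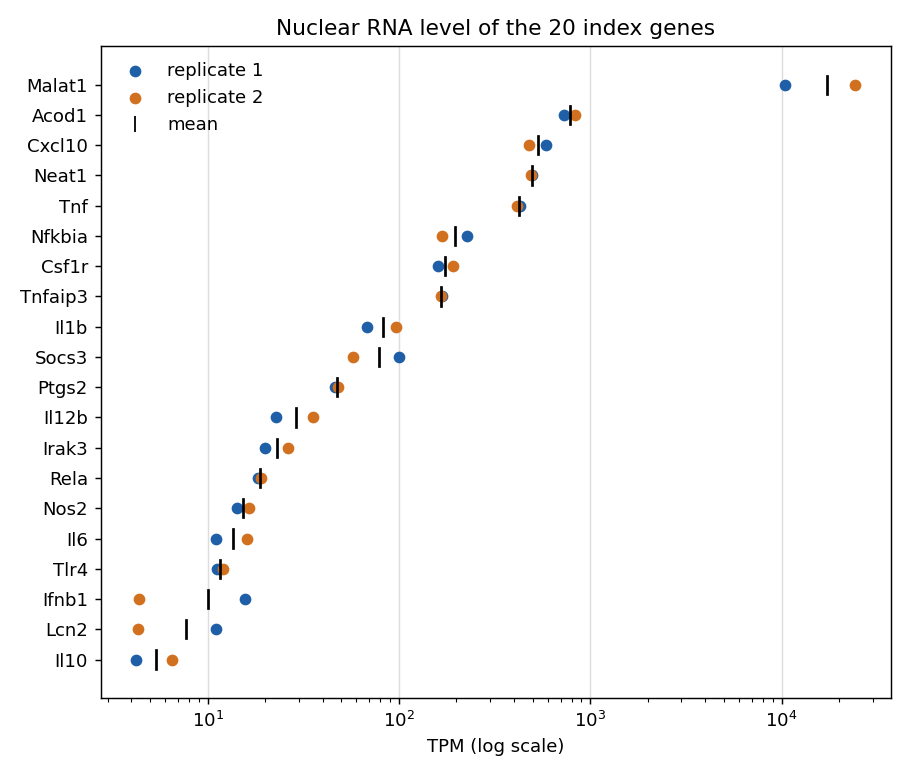
TPM (log scale) of the 20 index genes in the 2 nuclear libraries; points are replicates and black bars their mean. Among these genes the mean ran from 5.39 TPM for Il10 to 17255 TPM for Malat1, and the replicates lay furthest apart in relative terms for Ifnb1, at 15.8 and 4.38 TPM.

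Interferon-stimulated genes were expressed throughout. All 34 members had TPM 1 or more in both libraries, 19 of them 100 or more, and their median was 122 ± 8.74 TPM (percentile 100 in both). The antiviral genes Rsad2 (948 ± 108 TPM), Oasl2 (508 ± 161 TPM) and Ifit2 (501 ± 22.4 TPM) were highest. Antimicrobial and metabolic effectors had a median of 30.2 ± 0.219 TPM with 20 of 23 genes at TPM 1 or more in both. They were led by Saa3, an acute-phase protein, at 1282 ± 877 TPM (1902 in replicate 1 and 661 in replicate 2), by Acod1, the enzyme that makes itaconate (780.1 ± 75.7 TPM; chromosome 14, 103046977 to 103056573), and by the mycobacterial receptor Clec4e (428 ± 119 TPM). Ptgs2, the inducible cyclooxygenase, had 47.2 ± 1.51 TPM and Nos2, the inducible nitric oxide synthase, 15.3 ± 1.65 TPM. Lcn2, which binds bacterial siderophores, had 7.72 ± 4.79 TPM. The 9 inflammasome and pyroptosis genes had a median of 43.4 ± 7.07 TPM, with Nlrp3 at 115 ± 2.71 TPM and Casp4 at 77.1 ± 22.0 TPM.

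Negative regulators of the TLR4 and NF-kB pathways were expressed beside the cytokines. Of 20 such genes, 19 had TPM 1 or more in both libraries, with a median of 27.7 ± 0.0566 TPM (percentile 100 in both). That small SD holds on the TPM scale only. On TMM-scaled counts the list's median log2 ratio, replicate 2 over replicate 1, was -0.69 relative to the median of all genes. Tnip3 had 323 ± 79.6 TPM, Nfkbia, which encodes the inhibitor IκBα (chromosome 12, 55489410 to 55492647), 197 ± 41.5 TPM, and Tnfaip3, which encodes the ubiquitin-editing enzyme A20, 167 ± 0.919 TPM. Socs3 had 79.0 ± 29.9 TPM and Irak3, a kinase-dead inhibitor of the receptor's signalling, 23.1 ± 4.65 TPM. The median log2(TPM + 1) of these regulators was 0.48 ± 0.17 (n = 2) above that of the cytokines. This order turned to -0.53 when genes under TPM 1 in both libraries were left out, so it rests on the unexpressed cytokines. The cytokine median lay below that of the macrophage identity genes, with a difference of -2.34 ± 0.24 on the same scale.

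The receptor pathway and its transcription factors were present at moderate levels. All 20 genes of TLR4 and its signalling had TPM 1 or more in both libraries, with a median of 14.9 ± 4.88 TPM. Tlr4 itself had 11.7 ± 0.601 TPM, the co-receptor Cd14 196 ± 39.9 TPM and Irak2 67.9 ± 6.85 TPM. Among the 5 NF-kB subunits Nfkb1 (148 ± 43.1 TPM) was highest, and Rela had 18.7 ± 0.552 TPM. Other pattern recognition receptors had a median of 17.2 ± 0.297 TPM and were led by Tlr1 (189.7 ± 59.8 TPM), Tlr2 (104 ± 9.19 TPM) and Tlr7 (62.7 ± 0.0141 TPM). Immediate-early transcription factors, whose transcripts come and go within hours of a stimulus, had a median of 7.26 ± 0.378 TPM, with Klf6 at 151 ± 6.22 TPM, Junb at 65.9 ± 33.3 TPM and Atf3 at 49.2 ± 4.41 TPM.

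**Figure D3:**
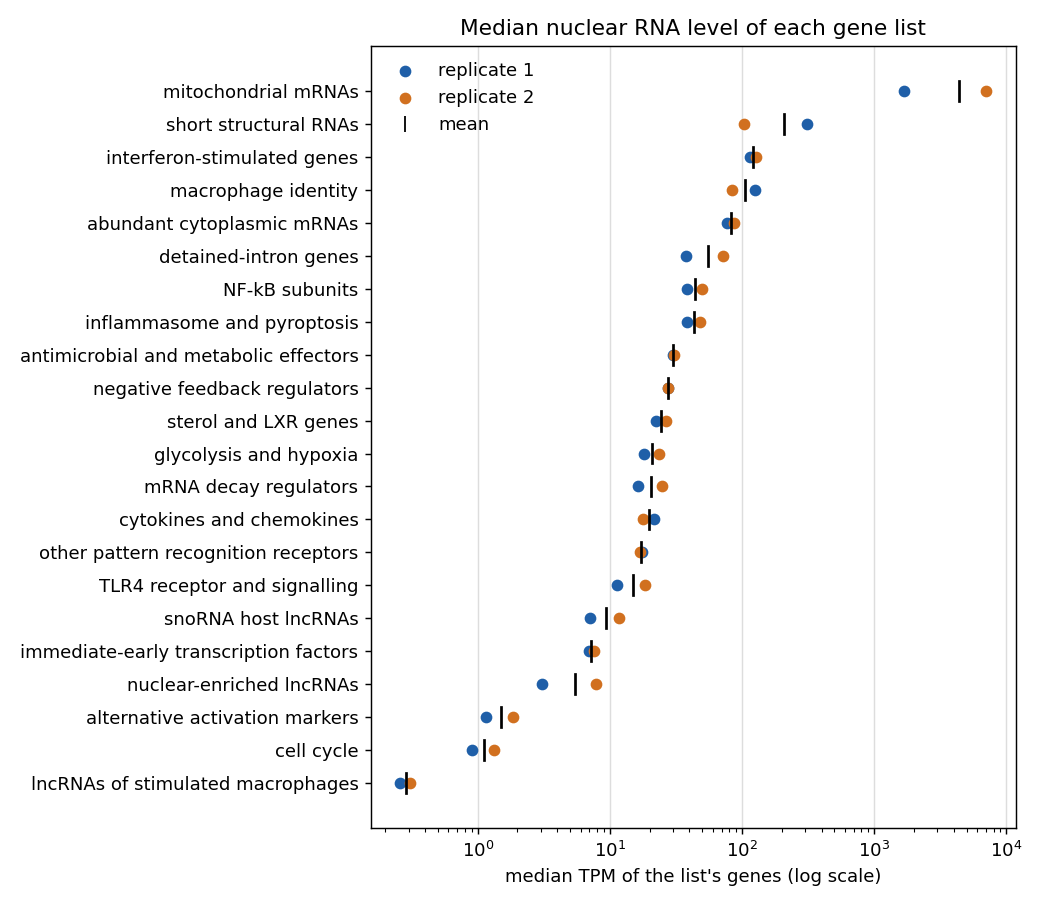
Median TPM (log scale) of each of 22 gene lists in the 2 nuclear libraries; points are replicates and black bars their mean. Interferon-stimulated genes (122 TPM) and macrophage identity genes (105 TPM) lay above the cytokines (19.6 TPM), and alternative activation markers (1.5 TPM) and cell cycle genes (1.12 TPM) lay near 1 TPM.

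Genes of macrophage identity were expressed, and markers of other cell types were near 0. The 23 macrophage identity genes had a median of 105 ± 29.8 TPM (percentile 100 in both), and 22 of them had TPM 1 or more in both libraries, led by lysozyme Lyz2 (1265 ± 50.4 TPM), the protease Ctss (879 ± 69.2 TPM) and Adgre1, which encodes the surface marker F4/80 (643 ± 150 TPM). The growth factor receptor Csf1r had 175 ± 22.3 TPM. In 7 of the 9 lists of other cell types every gene was below TPM 1 in both libraries: T cell, B cell, NK cell, neutrophil, fibroblast and stromal, dendritic cell, and mast cell, basophil and eosinophil markers. Of the 56 genes in these 9 lists only Kdr, an endothelial receptor, passed TPM 1 in both, at 10.1 ± 2.59 TPM, while the endothelial Pecam1 and Cdh5 had 0.545 ± 0.00707 and 0.155 ± 0.0354 TPM. The erythroid Alas2 had 0.84 TPM in replicate 1 and 1.77 in replicate 2, and Hba-a1 had 1 and 0 counts. The second tool gave higher values in replicate 2 for a few of these markers, 14.4 TPM for Pecam1, 5.57 for Cd3d and 3.41 for Alas2.

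Alternative activation markers stood inside the middle 95% of random lists, with a median of 1.5 ± 0.481 TPM (percentiles 79.3 in replicate 1 and 79.9 in replicate 2) and 7 of 13 genes at TPM 1 or more in both. Stab1 (58.7 ± 2.60 TPM), Il4ra (38.3 ± 3.33 TPM) and Tgm2 (30.8 ± 7.07 TPM) led that list. Cell cycle genes were similar, with a median of 1.12 ± 0.290 TPM and percentiles of 81.2 and 78.1. Pcna (25.9 ± 12.0 TPM) and Mki67 (18.8 ± 0.361 TPM) were the highest of them. Of the 69 replication-dependent histone genes, 38 were below TPM 1 in both, and Hist2h2aa2 (25.1 ± 18.1 TPM), Hist3h2a (11.1 ± 0.332 TPM) and Hist1h4m (8.20 ± 1.68 TPM) were highest. Members of histone families share sequence, so these values are uncertain.

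Metabolic and housekeeping lists lay between. Genes of glycolysis and hypoxia had a median of 20.9 ± 3.79 TPM, led by Pkm (78.1 ± 15.0 TPM), Aldoa (46.1 ± 0.431 TPM) and Ldha (40.2 ± 3.30 TPM). Sterol and LXR genes had 24.4 ± 3.07 TPM, led by the cholesterol exporters Abca1 (112 ± 18.3 TPM) and Abcg1 (41.8 ± 0.325 TPM). The small SDs of Abcg1 and Aldoa do not show close replicates. Abcg1 had 10243 counts in replicate 1 and 3860 in replicate 2. Its log2 ratio on TMM-scaled counts was -0.83 relative to the median of all genes. In TPM rescaled without short and mitochondrial RNAs, Abcg1 had 168.7 ± 43.3 and Aldoa 186 ± 47.4. Abundant cytoplasmic mRNAs had a median of 82.0 ± 7.15 TPM, with Fth1 at 1652 ± 306 TPM, Actb at 1426 ± 282 TPM and B2m at 1036 ± 182 TPM. Regulators of mRNA decay had 20.6 ± 6.07 TPM, with the RNase Zc3h12a at 31.5 ± 3.37 TPM and the AU-rich element binder Zfp36 at 57.4 ± 21.3 TPM.

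Nuclear long non-coding RNAs were dominated by few genes. After Malat1, the paraspeckle RNA Neat1 (chromosome 19, 5824708 to 5845478) had 494 ± 7.16 TPM and Xist, the RNA of the inactive X chromosome, 114 ± 90.1 TPM, while the list's median was 5.45 ± 3.34 TPM. Among the 5 long non-coding RNAs of stimulated macrophages, Mir155hg, the precursor of miR-155, had 286 ± 121 TPM, and Ptgs2os2 and Ptgs2os had 0.520 ± 0.0141 and 0.285 ± 0.0354 TPM. Hosts of snoRNAs had a median of 9.37 ± 3.20 TPM, led by Gas5 (45.0 ± 11.7 TPM), Snhg8 (24.8 ± 10.5 TPM) and Snhg20 (15.7 ± 2.76 TPM).

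Genes known to keep detained introns in the nucleus had a large share of their RNA on retained-intron transcripts. The median share over the 24 such genes measured was 49.7% ± 2.79 (n = 2), or 47.7% in replicate 1 and 51.6% in replicate 2. Random lists matched on expression, from 6942 genes with an annotated retained-intron transcript, had a median of 23.0% in replicate 1 (95% of lists from 14.7 to 33.1) and 29.9% in replicate 2 (18.7 to 41.8), and the list stood at percentiles of 100 and 99.98. Among the highest shares were those of the splicing factors Srsf11 (87.6% ± 3.54), Rbm5 (79.6% ± 8.68), Luc7l (70.3% ± 2.30) and Luc7l2 (66.8% ± 8.79). The share was higher in replicate 2 for 18 of the 24 genes. The second tool gave a median of 47.3% for the list. Ddx5, at 263 ± 58.5 TPM the most abundant gene of the list, had 2.94% ± 0.770. Such shares depend on how the tools divide reads between overlapping transcripts. They also depend on how many retained-intron transcripts are annotated for a gene, on which the random lists were not matched. Interferon-stimulated genes had a median share of 25.4% ± 7.14 and cytokines 19.8% ± 3.43.

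The 2 libraries differed in a patterned way. Relative to the median of all genes, 12 of the 13 mitochondrial mRNAs and 17 of the 27 detained-intron genes were higher in replicate 2 beyond counting error, while all 23 macrophage identity genes, 29 of 34 interferon-stimulated genes, 17 of 29 tested cytokines and 15 of 19 tested negative regulators were lower. Each of these counts rests on the exact binomial test, which compares these libraries and not conditions. On TMM-scaled counts the median log2 ratio, replicate 2 over replicate 1, was 1.46 for the mitochondrial mRNAs (percentile 100 of matched random lists) and 0.18 for the detained-intron genes (99.97). It was -0.79 for identity genes (0), -0.59 for interferon-stimulated genes (0.09), -0.62 for cytokines (0), -0.69 for negative regulators (0.02) and -0.84 for immediate-early factors (0). Short structural RNAs were lowest at -1.49 (0). On the TPM scale the directions relative to the median gene were the same for these lists, though the interferon-stimulated genes then lay inside the middle 95% of random lists (percentile 3.69). The ratio followed GC content, with a median of 0.83 in the 724 genes of lowest GC content and -0.58 in the 734 of highest. Against random lists matched on GC content the detained-intron genes stood at percentile 33.8, inside the middle 95%. Of 31 lists with a value, 10 lay outside that range by TPM, and 14 of 25 did so by TMM-scaled counts.

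Over all genes, 8711 of 14698 differed between the libraries beyond counting error, 4307 higher in replicate 2 and 4404 higher in replicate 1, so the libraries were not repeat deposits of 1 library. With library size in place of TMM, 63.8% of the differing genes were higher in replicate 2 against 49.4%. Within a factor of 2 lay 82.7% of the genes. Of the 20 index genes, 15 were lower in replicate 2 on this test, Malat1 was higher, and Il1b, Il6, Il10 and Il12b did not differ (adjusted p by the exact test 0.1001, 0.534, 1 and 0.954). By deposited TPM, 14 of the 20 were within 1.5-fold. Of those lower on the test, Acod1 had the higher TPM in replicate 2 (727 in replicate 1 and 834 in replicate 2). Cxcl10 had the lower TPM there too (585 and 480).

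The genes furthest apart included mitochondrial copies, a gene within the span of Malat1 and the second Rmrp gene. Whether the others share reads with copies or overlapping genes was not tested. Higher in replicate 2 were Gm28439 (0.7 and 63403 counts), Gm37376 (0 and 1596 counts), mt-Atp8 (5750 and 24786 counts), Gm18955 (75 and 298 counts) and Gm10222 (4012 and 15207 counts). Gm28439 and Gm10222 belong to the block of mitochondrial copies on chromosome 1, and Gm37376 lies within the span of Malat1 on the other strand. Lower in replicate 2 were B430305J03Rik (1522 and 0 counts), Gm26669 (238 and 7.22 counts), the second Rmrp gene (81433 and 3980 counts), Snord22 (202 and 10.9 counts) and the ribosomal RNA gene CT010467.1 (8016 and 479.5 counts). The second tool put B430305J03Rik and Gm10222 at 0 TPM in both libraries, Gm28439 at 273 and 3132 TPM, Gm37376 at 1009 and 2336 TPM, Gm26669 at 1.11 and 0.656 TPM, CT010467.1 at 1006 and 854 TPM and Snord22 at 103 and 32.1 TPM. It put mt-Atp8 at 1345 and 14103 TPM, Gm18955 at 2.82 and 24.5 TPM and the second Rmrp gene at 11834 and 964 TPM. In these raw values the direction was the same with both tools except for the 2 genes at 0. The size of the difference depended on the tool. The second tool's TPM is not set relative to the median of all genes. A gene lower on TMM-scaled counts can be higher on it, as Abca1 was (log2 ratio -0.32, but 43.3 and 74.4 TPM). A modest rise in that TPM, as for Gm37376, therefore does not by itself show a rise relative to other genes.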

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

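The phiX174 and tRNA rows lie outside the gene measurements and were singled out because their counts were above the 3 counts that a count of 0 allows, there being no control samples. phiX174, a bacteriophage genome used as a sequencing control, had 518475 counts in replicate 1 and 54031 in replicate 2. Predicted tRNA genes had 18 counts in replicate 1 and 28 in replicate 2 over 26248 rows. No group had the 4 samples that a search for outlying samples needs.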

How the results depend on the processing

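The differences between list medians depended on the settings. Regulators minus cytokines reversed to -0.53 when members under TPM 1 in both libraries were left out and was 1.54 with CPM in place of TPM, where length no longer counts. Cytokines minus identity genes moved to -1.59 and -3.26 under the same 2 settings and stayed negative under every alternative run. Genes detected numbered 5462 at TPM 5 or more, by construction of the stricter threshold. Genes differing between the libraries fell to 2325 when a 2-fold difference was also required. The coefficient of variation was 0.291 for genes with a mean count of 100 or more. For the moves in the list differences the cause was not tested beyond the settings' construction. Each library alone gave from 10674 to 12321 genes detected, from -2.51 to -2.17 for cytokines minus identity, from 0.36 to 0.60 for regulators minus cytokines and from 47.7 to 51.6% for the retained-intron share. With 2 libraries a single one always lies within 1 SD of the mean, so these ranges show no stability. Among 151 list medians and named genes, TPM rescaled without short and mitochondrial RNAs moved 141 by more than 1 SD, the second tool 103 and posterior mean TPM 46, so a TPM here is comparable only within 1 table and scaling. Rescaling raises every remaining TPM by construction, as for Csf1r from 175 to 695, and sets those left out to 0. An SD of 2 values can also be very small, so these counts do not measure the size of the moves. Matching random lists on GC content, added after the data were seen, put 14 lists outside the middle 95% on TMM-scaled counts, as matching on expression did, but only 12 lists were outside on the same side in both. Detained-intron genes and genes of glycolysis and hypoxia then lay inside, and antimicrobial effectors and inflammasome genes outside.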

Other observations

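Both libraries held Xist (50.1 TPM in replicate 1 and 177.5 in replicate 2), while the Y-linked Ddx3y, Uty, Eif2s3y and Kdm5d had 0 counts in both, below the floor of 3 counts. The second tool listed Uty at 1.75 and 7.70 TPM and Kdm5d at a mean of 1.87 TPM. The labels give no sex. Among the genes of the arginine and itaconate branches, chosen after their values were seen, Acod1 had 780.1 ± 75.7 TPM, Nos2 15.3 ± 1.65 TPM and Arg1 0.570 ± 0.354 TPM. Cx3cr1, a receptor of resident macrophages, was the only identity gene below TPM 1 in both gene tables, at 0.0850 ± 0.0495 TPM, against 0.245 and 1.94 TPM with the second tool, and of the cytokine list Csf3, Lif and Il23a were at 0.150 ± 0.0141, 0.0800 ± 0.0707 and 0.290 ± 0.198 TPM. For Il23a the second tool gave a mean of 2.22 TPM. The transcription factor Cebpb, also chosen after its values were seen, had a log2 ratio of -3.16 between the libraries on TMM-scaled counts. With the second tool's TPM + 1, a scale not set relative to the median of all genes, the log2 ratio was -1.37. The GC content of Cebpb is 67.2%.

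All patterns below concern 1 replicate against the other, which also differ in input amount, and were noticed in the data before they were tested. The tests with cytosolic mRNAs and nuclear copies were chosen after the values they use were seen. The tests with GC content, position in genes and transcript length were set out before their results were known. The design names no biological difference between the replicates, so none was tested, and the unspliced RNA weighed below is a property of the libraries whose origin was not tested. Ratios are on TMM-scaled counts, replicate 2 over replicate 1, relative to the median of all genes.

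Genes of low GC content were higher in replicate 2 and genes of high GC content lower. The median log2 ratio was 0.83 in the 724 genes of lowest GC content (median 37.0%) and -0.58 in the 734 of highest (60.4%). After subtraction of this trend the detained-intron genes went from 0.18 to -0.06 and stood at percentile 33.8 of GC-matched random lists, so their shift went with GC content. Identity genes went from -0.79 to -0.69, interferon-stimulated genes from -0.59 to -0.66, cytokines from -0.63 to -0.42 and negative regulators from -0.69 to -0.31, so more than 50% of the regulators' shift went with GC content. These 4 lists still stood at percentiles of 0.13 or below among GC-matched lists.

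The mitochondrial mRNAs were higher in replicate 2, with a median log2 ratio of 1.46. Reads moving between the mitochondrial genome and its nuclear copies do not account for it, since the sum over both was higher too, with a log2 ratio of 1.20, from 5.14% to 13.2% of all counts, and from 4.32% to 10.7% with the second tool. GC content may account for part: after subtraction of the GC trend 0.63 was left, which still lay at percentile 99.93 of GC-matched lists, so the values met neither of the outcomes set out in advance. Cytosolic RNA in the nuclear fraction would raise the abundant cytoplasmic mRNAs. All 16 were lower in replicate 2 beyond counting error, with a median log2 ratio of -0.37. That median stood at percentile 15.5 of expression-matched lists and 7.46 of GC-matched lists. Both lie inside the middle 95%, where the rule decides nothing, and the high level of these mRNAs in the fraction could hide a small rise. Cytosolic RNA therefore stays open. Mitochondria carried over without cytosol, input amount and handling stay open and were not tested.

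Genes typed TEC in the annotation (single loci still awaiting experimental evidence) and sense-intronic genes were higher in replicate 2, with a median log2 ratio of 0.93 over 1228 genes. GC content left most of it, with 0.65 after subtraction and percentile 100 of GC-matched lists. Of these genes, 846 lie inside a protein-coding gene on the same strand, where 94.2% were higher in replicate 2, against 78.1% of the 201 on the opposite strand or in partial overlap and 72.4% of the 181 outside protein-coding genes. The GC-adjusted medians were 0.72, 0.53 and 0.33 in that order, and the difference between same-strand and outside genes was 0.38 (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give, with genes that are not independent and a strand setting that is not given). More unspliced RNA of the surrounding protein-coding genes in replicate 2 could give that difference, as a hypothesis for part of the pattern. The genes outside protein-coding genes were higher too, and whether they lie inside non-coding genes was not examined. Retained-intron transcripts took 16.5% of the TPM of protein-coding genes in replicate 1 and 22.7% in replicate 2. These shares were not adjusted for GC content, which the ratio between the libraries followed, so they do not decide the question.

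Immediate-early transcription factors were lower in replicate 2, with a median log2 ratio of -0.84 and 16 of 19 tested genes lower beyond counting error. Their GC content is high (median 54.6%), but the list still stood at percentile 0.07 of GC-matched random lists, with -0.64 left after subtraction. Transcript length left it as it was, at -0.84 after subtraction of the median of genes of like length, percentile 0. A lower share of short-lived spliced mRNA, slightly different timing and input amount could each give this pattern and were not tested.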
